A study of Mus musculus with 24 samples.

How the data were processed

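Gene expression was measured with Affymetrix mouse arrays in jaw tissue of embryos at embryonic day 13.5. Mutant embryos carried a Wnt1-Cre transgene and a floxed Tgfbr2 gene, so that the type II TGF-beta receptor is deleted in the neural crest. Per the labels, mutants were recognised by a cleft palate and a skull vault defect, and controls were their littermates, whose Cre status is not given. Mandible and maxilla were each divided into a distal and a proximal end. The 24 arrays form 8 groups of 3 (2 genotypes, 2 jaws, 2 ends), and no array was left out. RNA was extracted with an RNeasy kit and biotin-labelled cRNA was made from 5 µg of total RNA, per the labels. The deposited values are on a log2 scale, per their range, and were made with RMA, per the submitters' processing notes. The version of RMA, which arrays were normalized together and whether embryos were pooled are not given in the sources used here. For arrays, their number limits the precision of each value.

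Of 45101 probe sets, 34958 name a single gene symbol, 932 name several and 9211 name none. The gene identifiers of 34754 probe sets matched a table of RefSeq genes (assembly GRCm38.p6, used for names and for the chromosome of a gene), and no symbol was changed. Each of the 18194 genes was represented by its probe set with the highest mean over the 24 arrays. A gene was kept when that probe set lay above the 40th percentile of its array on at least 3 arrays, which left 13850 genes. Where, in the average genotype effect or a control comparison, another probe set of a called named gene had a mean above the 40th percentile of all values and moved the opposite way, its value is given beside the gene. Opposite moves of dimmer probe sets are not given, except for Tgfbr2.

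limma 3.58.1 in R 4.3.3 was fitted to all 24 arrays with 1 coefficient per group and 16 residual degrees of freedom (lmFit, contrasts.fit and eBayes with its default settings). Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the 13850 genes. All adjusted p-values of single genes come from this fit unless another is named, and errors are standard errors (SE) of the log2 difference from its moderated variance unless marked as standard deviations (SD). The comparisons were the genotype effect (mutant minus control) in each of the 4 regions, its average over the regions, its difference between the jaws and between the ends, and, in control arrays, mandible minus maxilla and distal minus proximal in each jaw. The 4 arrays that share genotype and replicate number are called a set. Arrays of a set deviated together (random block correlation 0.40, from duplicateCorrelation with statmod 1.5.0), so counts of the average genotype effect are given with arrays as replicates, with the set as a random block and with 1 value per set.

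Control distal and proximal arrays of the same number also deviated together. The correlations of their deviations from the group means were 0.49, 0.44 and 0.41 in the mandible and 0.57, 0.24 and 0.22 in the maxilla, so the numbers were taken as pairs there, from the values and not from the labels. Counts with the replicate number as a block stand beside those results.

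The 33 gene lists were tested with camera (limma, preset correlation 0.01) where at least 5 members were tested, which left 32. Their p-values were adjusted over the lists of a comparison, and the tests were repeated with a correlation estimated per list. The lists are cartilage, bone, skeletal muscle, tendon, epithelium, neurons, Schwann cells, endothelium, red blood cells, macrophages, smooth muscle and pericytes, eye and pigment cells, brain and pituitary, Hox-expressing tissue and sex-linked genes. Further lists hold TGF-beta ligands, receptors and regulators, TGF-beta responsive genes, BMP, FGF, WNT and hedgehog signalling, endothelin and mandibular identity, maxillary identity, palate, tooth, neural crest mesenchyme, extracellular matrix, cell cycle, p53 targets, cholesterol synthesis, lipid storage and fat cells, hypoxia and glycolysis, and immediate early and heat shock genes. Some genes stand in more than 1 list, and the lists came from general knowledge, not from these samples. Of their 641 symbols, 596 were found among the gene names and 45 were not. List tests were planned for the average genotype effect and the control comparisons. Those within single regions and on differences of effects were not planned.

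The genes named in the text were chosen by rule. Tgfbr2 came first. In each comparison the rule took the 10 largest rises and the 10 largest falls in log2 fold among called genes whose compared arrays did not overlap within any region compared. For the average genotype effect and the jaw comparison arrays could overlap, and instead the difference of means had to have the same sign in all 4 regions or at both ends. For single regions the text stops at 5 each way. Differences of effects would have given the 5 smallest p each way. Each list described gives up to 4 members with the smallest p. Genes with only a clone, predicted or locus name are counted and not named, and any gene outside the rule is said to be chosen after its values were seen. With 3 arrays against 3, chance leaves a gene's arrays without overlap in 10% of cases.

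The comparisons, the tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The alternatives fixed then were no filter, the mean of all probe sets of a gene, quantile normalization again, eBayes with trend and robust, array weights, a replicate block, a random block, only the groups of the contrast, an estimated correlation in camera and leaving out each array. Alternatives chosen after seeing the data were 1 value per set, leaving out whole sets, leaving out mutant sets 1 and 3, the Gapdh 3' to 5' difference as a covariate, no genes of the X and Y chromosomes, gene-by-gene array weights, a filter on the probe set mean, and the list tests with the random block.

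The code was tested on simulated data with 13850 genes, of which 100 changed by log2 0.5 and 100 by log2 1. With independent arrays, the genotype effect in the distal mandible recovered 55% and 93% of these, with 11 false calls among 13625 unchanged genes, and the average effect recovered 91% and 100%, with 10 false calls. With arrays of a set correlated, the average effect gave 556 false calls with arrays as replicates, 16 with the random block and 3 with 1 value per set. Python 3.11.15 with matplotlib 3.10.9 drew the figures.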

Results

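Expression was profiled on 24 arrays from the jaws of mouse embryos in which Tgfbr2, the type II receptor for TGF-beta, is deleted in the neural crest, and from control littermates. The samples form 8 groups of 3 arrays, one for each genotype and region (distal mandible, proximal mandible, distal maxilla and proximal maxilla). The labels do not say whether replicates come from separate animals, so the p-values measure the spread between these samples, which may be technical in part. In both genotypes the sex-linked transcripts below set replicate 1 apart from replicates 2 and 3, so these are not repeats of a single sample. The 4 arrays that share genotype and replicate number, here called a set, are likewise of unstated origin. Their sex-linked transcripts were alike within each set.

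Sex-linked transcripts and the Gapdh control probe sets differed between sets. Xist, the RNA of the inactive X chromosome, averaged log2 6.31 in control set 1, 13.68 in control set 2 and 13.65 in control set 3 (n = 4 arrays each). The mean of Eif2s3y, Kdm5d and Uty, genes of the Y chromosome, was 9.97, 3.82 and 3.88 in those sets. In mutant set 1 Xist was at 6.50 and the Y-linked mean at 10.01, while mutant sets 2 and 3 held both kinds of transcript (Xist 13.52 and 13.19, Y-linked mean 8.81 and 9.20). Every array of mutant sets 2 and 3 held both at these high levels, and no control array did. The 3' minus 5' difference of the Gapdh probe sets, which rises as RNA degrades, was 0.04 ± 0.0671 in control arrays (SD, n = 12), 0.06 ± 0.0273 in mutant set 2 (SD, n = 4) and 0.50 ± 0.193 in mutant sets 1 and 3 (SD, n = 8). Every array of mutant sets 1 and 3 (0.25 to 0.77) lay above every control array (-0.07 to 0.16).

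**Figure D1:**
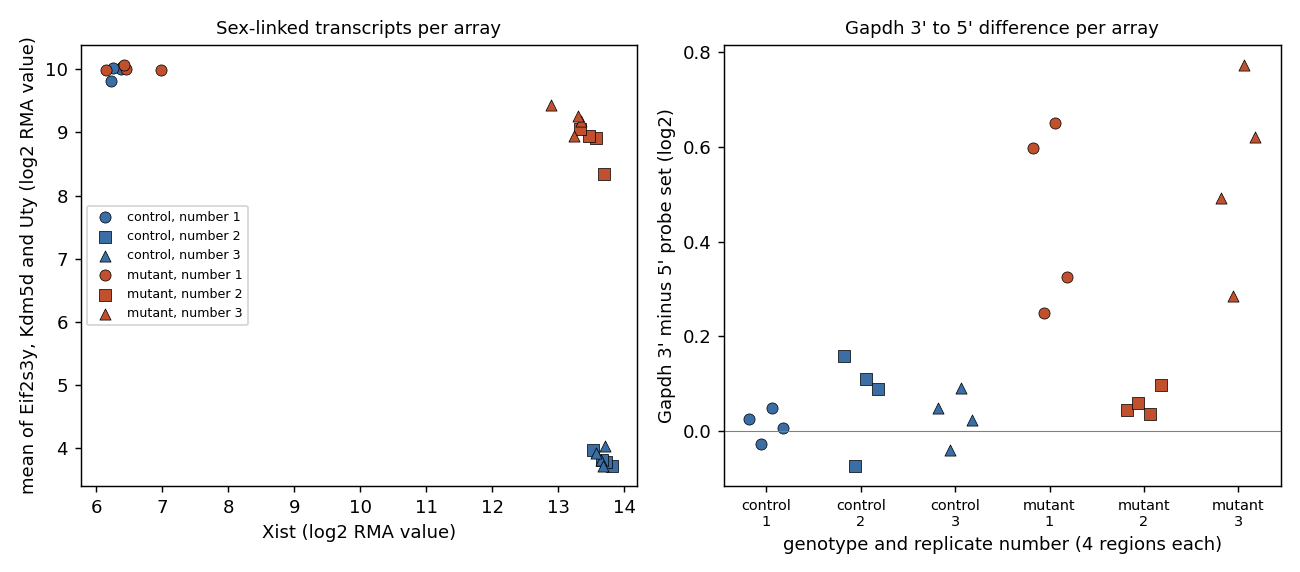
Left, log2 signal of Xist (x axis) against the mean log2 signal of 3 Y-linked genes (y axis), 1 point per array; right, log2 difference between the 3' and 5' Gapdh probe sets per array, by set. Control set 1 and mutant set 1 have low Xist, mutant sets 2 and 3 have both kinds of transcript, and the 8 arrays of mutant sets 1 and 3 lie between 0.25 and 0.77 in the Gapdh difference, above all 12 control arrays.

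Tgfbr2, the deleted gene, read slightly higher in mutant arrays. Its brightest probe set averaged log2 12.42 in mutant and 12.11 in control arrays (SD 0.13 and 0.116, n = 12 each), a difference of 0.31 ± 0.0543 (adjusted p = 0.000296). Within regions the difference was 0.36, 0.20, 0.36 and 0.32 (SE 0.109, n = 3) in distal mandible, proximal mandible, distal maxilla and proximal maxilla, and it passed in no region (adjusted p = 0.118, 0.341, 0.0523 and 0.0889). The other probe sets gave -0.18 (adjusted p = 0.236, mean log2 7.06) and -0.06 (adjusted p = 0.355, mean log2 3.79). Where the probes lie relative to the deleted part of the gene is not given in the sources used here, so these values check neither the deletion nor the labels. The call of the brightest probe set was lost with 1 value per set (adjusted p = 0.0903), and the proximal mandible value turned to -0.058 with the mean of all probe sets.

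The first question was which genes differ between mutant and control jaws on average over the 4 regions (n = 12 arrays from 3 sets per genotype). Among the largest rises was Vit, which encodes the matrix protein vitrin, at 2.68-fold (log2 1.42 ± 0.106). Also higher were the opposite-strand transcript Cep83os at log2 1.21 ± 0.133, the zinc finger gene Zfp804a at 1.15 ± 0.13, the matrix gene Sned1 at 1.15 ± 0.172 and the ephrin receptor gene Epha5 at 1.10 ± 0.0817. Dmp1, a matrix protein of osteocytes, rose 2.01-fold (log2 1.00 ± 0.161), with regional differences from 0.06 to 2.51, and Tnfrsf11b, the osteoclast inhibitor osteoprotegerin, rose 1.99-fold. Among the largest falls were Scx, a transcription factor of tendon progenitors, at log2 -1.24 ± 0.104, and the tendon matrix gene Thbs4 at -1.36 ± 0.186. Fbln5, which is needed to assemble elastic fibres, fell by 1.22 ± 0.0646 and to 0.428 of the control level. With arrays as replicates, the adjusted p of these genes lay between 9.17e-10 (Fbln5) and 0.00019 (Tnfrsf11b). That fit counts the arrays of a set, which deviated together, as separate samples, so these p-values can be too small.

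Lyz2, the lysozyme of macrophages, changed by log2 -1.11 ± 0.0945, the lectin gene Clec4a3 by -1.20 ± 0.089, the toll-like receptor gene Tlr1 by -1.36 ± 0.171 and Lyz1 by -0.88 ± 0.0982. The cytokine gene Il33 (-0.98 ± 0.128), the fatty acid binding protein gene Fabp4 (-1.33 ± 0.243) and the transcriptional co-regulator gene Cited1 (-0.91 ± 0.0809) were lower as well. The Y-linked Eif2s3y, Kdm5d and Uty gave the largest differences (log2 3.84 ± 1.04, 3.50 ± 0.974 and 3.03 ± 0.88), which follow the sex transcripts of the sets, control set 1 reading like the mutants. All 3 calls were lost with 1 value per set (adjusted p = 0.256, 0.267 and 0.283). Of the other named genes, Cep83os, Dmp1, Tnfrsf11b, Tlr1, Fabp4 and Lyz1 also lost the call with 1 value per set (adjusted p = 0.0544 to 0.074).

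**Figure D2:**
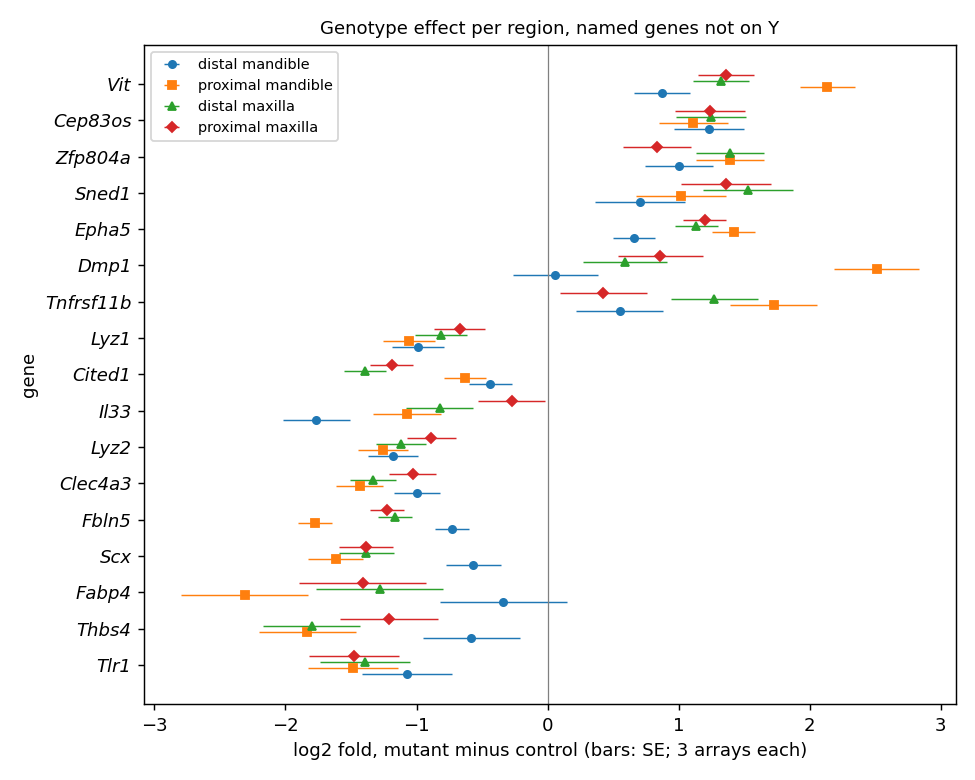
Log2 difference between mutant and control (x axis) for the 17 genes with the largest average changes besides the 3 Y-linked ones, in each of the 4 regions, with SE (n = 3 arrays per group). Fbln5 lies between -0.73 and -1.78 in all 4 regions, while Dmp1 ranges from 0.06 to 2.51.

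In all, limma called 2529 genes higher and 2142 lower in mutant arrays (4671 of 13850) with arrays as replicates, 771 and 841 (1612) with the set as a random block and 43 and 37 (80) with 1 value per set. Leaving out control set 1 or control set 3 gave 2902 and 3076 calls with arrays as replicates, and leaving out mutant set 2, the set without the raised Gapdh difference, gave 6971. With the Gapdh difference as a covariate, 2426 genes were higher and 3419 lower (2705 shared with the 4671), and without mutant sets 1 and 3 there were 2678 higher and 3919 lower (2835 shared). Lower genes thus outnumber higher ones in both, alternatives that were chosen after seeing the data. The Gapdh difference is raised only in mutant sets 1 and 3, so both rest largely on mutant set 2 and are not independent checks. Of the alternatives fixed in advance, the mean of all probe sets gave 1513 higher and 2209 lower. Quantile normalization again gave 2411 higher and 2216 lower.

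Genes of hypoxia and glycolysis rose together. Of 24 tested, 18 rose, 0 fell and 6 did not pass, 21 rose when adjusted over the list alone and 12 rose with the random block. Among them were the glycolytic regulator Pfkfb3 (log2 0.51 ± 0.0599), the oxygen sensor Egln3 (0.48 ± 0.0629), the pyruvate dehydrogenase kinase Pdk1 (0.55 ± 0.0742) and the vasodilator peptide gene Adm (0.61 ± 0.0873). The list was higher against other genes (camera, adjusted p = 1.56e-07), a call that was lost at adjusted p = 0.327 with an estimated correlation. The list's median difference from control was 0.34 and 0.24 in mutant sets 1 and 3, which have the raised Gapdh difference, and 0.21 in mutant set 2, which has not. Genes of the cell cycle fell: 15 of 31 were lower, 1 was higher and 15 did not pass, with 16 lower and 1 higher when adjusted over the list alone and 8 lower with the random block. The survivin gene Birc5 (-0.29 ± 0.038), the replication clamp Pcna (-0.20 ± 0.027), the mitotic kinase Aurkb (-0.25 ± 0.0341) and the cyclin Ccnb2 (-0.27 ± 0.0388) were among them. Camera called this list lower (adjusted p = 1.24e-05), and the call was lost at adjusted p = 0.327 with an estimated correlation. Its median was -0.07 and -0.10 in mutant sets 1 and 3 and -0.17 in mutant set 2. These 8 genes lost the call with 1 value per set (adjusted p = 0.0565 to 0.096).

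No other list was called for the average effect in camera. Besides genes already named, only Tgfb2, Nid1 and Cldn5 among the list members given here kept the call with 1 value per set. Among 30 ligands, receptors and regulators of the TGF-beta pathway, 12 rose, 2 fell and 16 did not pass (15 and 2 when adjusted over the list alone, 4 and 0 with the random block, adjusted p = 0.0975). The ligand Tgfb2 rose by log2 0.66 ± 0.0562, the co-receptor Tgfbr3 by 0.34 ± 0.0675 and the integrin Itgav by 0.27 ± 0.0347, although another probe set of Itgav read -0.12. Of 27 TGF-beta responsive genes, 5 rose, 6 fell and 16 did not pass (6 and 6 when adjusted over the list alone, 0 and 3 with the random block, adjusted p = 0.879), and their median was 0.03 while their mean was -0.05. Besides Scx, the matricellular gene Ccn1 (-0.46 ± 0.08) and Id1 (-0.38 ± 0.0767) fell, and the collagen Col3a1 rose (0.14 ± 0.0285). In the tendon list 2 of 14 rose and 4 fell (2 and 5 when adjusted over the list alone, 1 and 3 with the random block, adjusted p = 0.445). Its tendon regulator Mkx fell by 0.46 ± 0.0856, and Col12a1 rose by 0.34 ± 0.052 with another probe set at -0.15. Of 32 extracellular matrix genes, 13 rose, 4 fell and 15 did not pass (14 and 4 when adjusted over the list alone, 4 and 2 with the random block, adjusted p = 0.153). The basement membrane genes Nid1 (0.45 ± 0.0403) and Col4a1 (0.37 ± 0.0474) rose and the elastic fibre gene Emilin1 fell (-0.41 ± 0.0543).

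Markers of blood and vessels moved in both directions. Of 15 macrophage genes, 2 rose and 6 fell (the same counts when adjusted over the list alone, 0 and 2 with the random block, adjusted p = 0.0611). Besides Lyz2, Aif1 (-0.33), Coro1a (-0.41) and the leukocyte antigen Ptprc (-0.34) fell. In the red blood cell list 0 of 9 rose and 4 fell (0 and 4 when adjusted over the list alone, 0 and 0 with the random block, adjusted p = 0.193). These included the globins Hba-a2 (-0.79), Hbb-bh1 (-0.58) and Hba-x (-0.31). Of 18 endothelial genes, 4 rose and 6 fell (5 and 6 when adjusted over the list alone, 1 and 2 with the random block, adjusted p = 0.948, median 0.10 with camera's direction down). The tight junction gene Cldn5 (-0.42) and Pecam1 (-0.31) fell, and Plvap (0.37) and Cdh5 (0.27) rose. Among smooth muscle and pericyte genes 5 of 10 rose and 1 fell (6 and 1 when adjusted over the list alone, 2 and 0 with the random block, adjusted p = 0.153). Pdgfrb and Notch3 each rose by 0.30, and Tagln was at -0.32.

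BMP signalling had 5 of 25 higher and 5 lower (the same when adjusted over the list alone, 1 and 1 with the random block, adjusted p = 0.915). Its antagonist Chrdl1 rose (0.59) and Grem1 fell (-0.39), and the list had a median of -0.01 and a mean of 0.01. FGF signalling had 6 of 20 higher and 1 lower (6 and 1 when adjusted over the list alone, 3 and 0 with the random block, adjusted p = 0.641). Higher members were the feedback inhibitor Spry4 (0.30) and the receptor Fgfr1 (0.29, another probe set at -0.29). WNT signalling had 5 of 30 higher and 3 lower (4 and 2 when adjusted over the list alone, 1 and 0 with the random block, adjusted p = 0.948). Here the receptor Fzd2 rose (0.25) and Lgr5 fell (-0.39), and the mean was 0.02 with a median of -0.00. Hedgehog signalling had 2 of 15 higher (1 when adjusted over the list alone, 0 with the random block, adjusted p = 0.153), Sufu (0.30, another probe set at -0.01) and Foxd2 (0.56). Of 17 p53 targets 7 were higher and 1 lower (8 and 1 when adjusted over the list alone, 1 and 0 with the random block, adjusted p = 0.153). Rises were seen for the apoptosis gene Pmaip1 (0.72) and Ccng1 (0.32, another probe set at -0.13). Cholesterol synthesis had 2 of 20 higher and 4 lower (2 and 4 when adjusted over the list alone, 0 and 3 with the random block, adjusted p = 0.37). Falls were seen for Fdps (-0.54) and Cyp51 (-0.29, another probe set at 0.06). In lipid storage and fat cells 3 of 19 were higher and 2 lower (2 and 2 when adjusted over the list alone, 1 and 1 with the random block, adjusted p = 0.915). Cebpb rose (0.45) and Fabp4 fell, and the mean was -0.04 with camera's direction up. Immediate early and heat shock genes had 5 of 21 higher and 1 lower (3 and 1 when adjusted over the list alone, 0 and 1 with the random block, adjusted p = 0.542). Junb rose (0.23) and Ier2 fell (-0.33).

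Neural crest mesenchyme had 6 of 17 higher and 0 lower (the same when adjusted over the list alone, 1 with the random block, adjusted p = 0.153). The transcription factor genes Snai1 (0.39) and Tfap2a (0.30) were among them. The palate list had 4 of 25 higher and 2 lower (2 and 2 when adjusted over the list alone, 0 and 0 with the random block, adjusted p = 0.74). Its transcription factor genes Sim2 (-0.85) and Meox2 (-0.61) were lower. Maxillary identity had 4 of 18 higher (1 when adjusted over the list alone, 0 with the random block, adjusted p = 0.74), including Nr2f1 (0.38). Endothelin and mandibular identity had 1 of 14 higher and 1 lower (the same when adjusted over the list alone, 0 and 1 with the random block, adjusted p = 0.453), Rgs5 (0.51) and Cited1. The tooth list had 4 of 21 higher and 1 lower (4 and 1 when adjusted over the list alone, 1 and 0 with the random block, adjusted p = 0.915), including the ectodysplasin gene Eda (0.32, another probe set at -0.13). Bone had 3 of 16 higher (3 when adjusted over the list alone, 2 with the random block, adjusted p = 0.74), Dmp1, Cdh11 (0.16) and Col1a2 (0.09). Epithelium had 3 of 24 higher and 1 lower (2 and 0 when adjusted over the list alone, 0 with the random block, adjusted p = 0.542), including Cdh1 (0.32) and Cdh3 (-0.23). Schwann cells had 3 of 9 higher (3 when adjusted over the list alone, 0 with the random block, adjusted p = 0.445), including Erbb3 (0.20) and Sox10 (0.27, another probe set at -0.08). Skeletal muscle had 0 of 31 higher and 2 lower (0 when adjusted over the list alone and with the random block, adjusted p = 0.445), Myh7 (-0.55) and Chrnd (-0.15). Eye and pigment cells had 1 of 7 higher (1 when adjusted over the list alone, 0 with the random block, adjusted p = 0.453), Crybb1 (0.17).

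No tested member passed in limma for 22 cartilage genes (adjusted p = 0.598), 16 neuronal genes (0.948), 7 genes of Hox-expressing tissue (0.542) or 5 genes of brain and pituitary (0.74, median -0.06, mean 0.11). Too few sex-linked genes were tested for camera (4); Eif2s3y, Kdm5d and Uty were higher and Xist was not called (-0.15, adjusted p = 0.951).

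**Figure D3:**
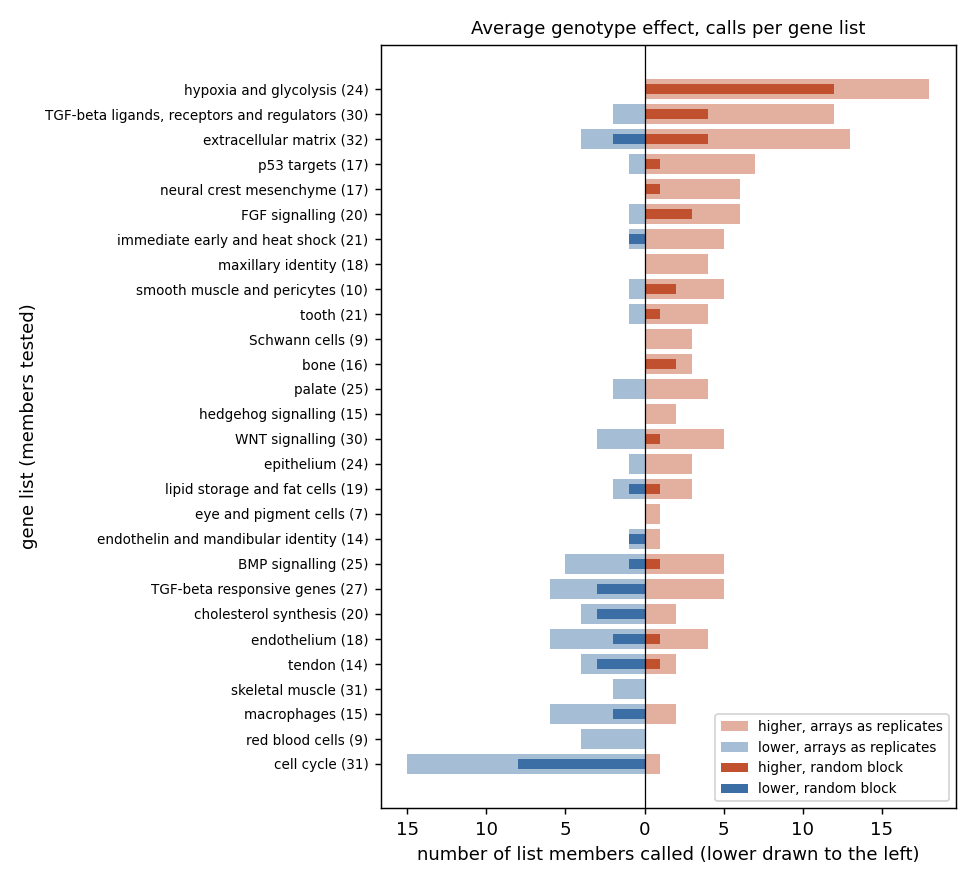
Number of genes called higher (right) and lower (left) in mutant jaws for the 28 lists with at least 1 call, with arrays as replicates (light) and with the set as a random block (dark). Hypoxia and glycolysis shows 18 higher and 0 lower of 24, and cell cycle 1 higher and 15 lower of 31; both are called by camera, and neither with an estimated correlation.

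The next question was the genotype effect within each region (n = 3 arrays per genotype). In the distal mandible the cytokine gene Il33 fell most (log2 -1.76 ± 0.257, adjusted p = 0.00778), followed by Lyz2 (-1.18 ± 0.189, adjusted p = 0.0118), Serinc4 (-1.03 ± 0.202), the interferon-induced gene Usp18 (-1.01 ± 0.215) and Clec4a3 (-0.997 ± 0.178). Cep83os (1.23 ± 0.266), the matricellular gene Smoc1 (0.94 ± 0.202), the potassium channel subunit Kcne3 (0.82 ± 0.185), Ndufa4l2 (0.76 ± 0.155) and the protease inhibitor Tfpi2 (0.73 ± 0.162) rose, at adjusted p of 0.0298 to 0.0439. In all 50 genes were higher and 74 lower. In the hypoxia and glycolysis list 2 of 24 rose, Egln3 and Pfkfb3, and 14 did when adjusted over the list alone (camera, adjusted p = 4.59e-08, and adjusted p = 0.38 with an estimated correlation). Camera also called skeletal muscle (0 of 31 passing, median 0.73, adjusted p = 6.19e-06), extracellular matrix (Nid1 higher and Fbln5 lower of 32, adjusted p = 0.0133) and TGF-beta ligands, receptors and regulators (0 of 30 passing, adjusted p = 0.0472) higher, at adjusted p = 0.629, 0.629 and 0.287 with an estimated correlation. It called macrophages (Lyz2 of 15, adjusted p = 0.0139) and cell cycle (0 of 31 passing, adjusted p = 0.0149) lower, both at adjusted p = 0.629 with an estimated correlation. Leaving out control array 1, 2 or 3 of this region gave 7, 19 and 12 calls in place of 124, and leaving out mutant array 1, 2 or 3 gave 19, 877 and 7. With only the 6 arrays of the region 1 gene was called, and with the random block 68. Of the largest rises and falls named for this region, list members aside, Smoc1, Ndufa4l2, Tfpi2, Serinc4 and Usp18 lost the call with the random block (adjusted p = 0.0611 to 0.0794).

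In the proximal mandible Dmp1 rose by log2 2.51 ± 0.321 (adjusted p = 0.000347), Vit by 2.13 ± 0.212 (adjusted p = 1.7e-05), Tnfrsf11b by 1.73 ± 0.332, the thyrotropin-releasing hormone receptor gene Trhr by 1.59 ± 0.446 and Epha5 by 1.42 ± 0.163. The prokineticin receptor gene Prokr2 fell by 2.38 ± 0.327 (adjusted p = 0.000712), Fabp4 by 2.31 ± 0.486, Thbs4 by 1.83 ± 0.372, Fbln5 by 1.78 ± 0.129 (adjusted p = 2.41e-07) and Atp1b4 by 1.65 ± 0.251. Scx was lower there too (-1.62 ± 0.209, adjusted p = 0.000359), but the tendon list had 2 of 14 higher and 2 lower and was not called (camera adjusted p = 0.866). In this region 395 genes were higher and 347 lower. Of 16 bone genes 2 rose, Dmp1 and Cdh11, and 5 when adjusted over the list alone, with a list median of 0.52 (camera, adjusted p = 0.000106, and adjusted p = 0.35 with an estimated correlation). Hypoxia and glycolysis had 4 of 24 higher (9 when adjusted over the list alone), camera adjusted p = 3.36e-07 and adjusted p = 0.35 with an estimated correlation. Cell cycle had 4 of 31 lower (5 when adjusted over the list alone), camera adjusted p = 0.000127 and adjusted p = 0.415 with an estimated correlation. Macrophages had 1 of 15 lower, Lyz2 (3 when adjusted over the list alone), camera adjusted p = 0.00146 and adjusted p = 0.793 with an estimated correlation. Without control array 1 or 3 of this region 139 and 341 genes were called in place of 742, and without mutant array 1, 2 or 3 470, 289 and 201. With only the 6 arrays of the region 283 genes were called.

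In the distal maxilla the follistatin-like gene Fstl5 rose by log2 3.06 ± 0.866 (adjusted p = 0.0394), Sned1 by 1.53 ± 0.343, Zfp804a by 1.39 ± 0.26, the enamel protein gene Ambn by 1.38 ± 0.409 and Vit by 1.32 ± 0.212. Sim2 fell by 1.87 ± 0.436 (adjusted p = 0.0163), Thbs4 by 1.80 ± 0.372, Tceal7 by 1.68 ± 0.466, Cited1 by 1.39 ± 0.162 (adjusted p = 0.000299) and Tlr1 by 1.39 ± 0.342. A total of 418 genes were higher and 562 lower. Of 24 hypoxia and glycolysis genes 6 rose, including Vegfa and Pdk1 (12 when adjusted over the list alone; camera adjusted p = 1.69e-06, and adjusted p = 0.421 with an estimated correlation). Of 31 cell cycle genes 7 fell, including Ccnb2 and Birc5 (9 when adjusted over the list alone; camera adjusted p = 0.000218, and adjusted p = 0.421 with an estimated correlation). Of 15 macrophage genes 3 fell, Lyz2, Aif1 and Tyrobp (7 when adjusted over the list alone; camera adjusted p = 6.28e-05, and adjusted p = 0.474 with an estimated correlation). Camera also called hedgehog signalling (Gli2 higher of 15, adjusted p = 0.00772), neural crest mesenchyme (Snai1 and Tfap2a higher of 17, adjusted p = 0.013) and cartilage (0 of 22 passing, median 0.75, adjusted p = 0.0159) higher, at adjusted p = 0.421, 0.328 and 0.835 with an estimated correlation. Skeletal muscle was called lower (0 of 31 passing, median -0.74, adjusted p = 1.04e-06, and adjusted p = 0.639 with an estimated correlation). Leaving out control array 1, 2 or 3 gave 421, 445 and 289 calls in place of 980, and leaving out mutant array 1, 2 or 3 gave 491, 1692 and 550. With only the 6 arrays of the region limma called 0 genes (2059 at an unadjusted p under 0.05). Of the largest rises and falls named for this region, list members aside, Fstl5 and Ambn lost the call with the random block (adjusted p = 0.0572 and 0.0848).

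In the proximal maxilla the cyclin gene Ccnb3 rose by log2 2.00 ± 0.267 (adjusted p = 0.000665), Pmaip1 by 1.78 ± 0.385, the arginase gene Arg1 2.83-fold (SE 0.4 on the log2 scale), the sialyltransferase gene St8sia6 by 1.37 ± 0.385 and Slc44a3 by 1.37 ± 0.265. Prokr2 fell by 1.61 ± 0.327 (adjusted p = 0.00957), Tlr1 by 1.48 ± 0.342, Scx by 1.39 ± 0.209, Fbln5 by 1.23 ± 0.129 (adjusted p = 5.07e-05) and Cited1 by 1.19 ± 0.162. The call covered 460 genes higher and 329 lower. Epithelial genes rose, 4 of 24 (7 when adjusted over the list alone), Cdh1 (0.90 ± 0.161), Esrp2 (0.78 ± 0.166), Dsp and Grhl2, with camera adjusted p = 0.000463 and adjusted p = 0.348 with an estimated correlation. Hypoxia and glycolysis had 5 of 24 higher, including Adm (0.97 ± 0.175) and Slc2a1 (9 when adjusted over the list alone; camera adjusted p = 2e-04, and adjusted p = 0.395 with an estimated correlation). Cell cycle had 5 of 31 lower, including Birc5 and Pcna (10 when adjusted over the list alone; camera adjusted p = 3.77e-07, and adjusted p = 0.348 with an estimated correlation). Without control array 1, 2 or 3 of this region 269, 385 and 214 genes were called in place of 789, and without mutant array 1 314. With only the 6 arrays of the region 5 genes were called. Of the largest rises and falls named for this region, list members aside, Arg1 and St8sia6 lost the call with the random block (adjusted p = 0.077 and 0.0973).

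Across the regions 58 genes were called in all 4, 19 higher and 39 lower, where independent lists of these sizes would share 0.00143 and 0.00179. Part of that excess may come from the sets, since the arrays of a set deviated together. They include genes named before (Fbln5, Clec4a3, Lyz2, Cep83os, Nid1, Pfkfb3, Kcne3 and Tfpi2). H2az2, a histone variant gene chosen after its values were seen, was among those lower by nearly the same amount in every region, at log2 -0.74, -0.92, -0.74 and -0.75 in distal mandible, proximal mandible, distal maxilla and proximal maxilla (adjusted p = 8.93e-06, 2.16e-07, 9.22e-06 and 3.4e-06). Also chosen after their values were seen, Pygl, a glycogen phosphorylase, was higher by 0.62, 1.07, 0.56 and 1.00, Plekha2 was higher by 0.57, 1.00, 0.79 and 1.21, and Rasl11b was lower (-0.55, -1.39, -0.45 and -1.05). Another 217 genes were called in 3 regions, 364 in 2 and 1024 in 1. The test of whether the genotype effect differs between the jaws or between the ends called 0 genes in limma each time (480 and 430 genes at an unadjusted p under 0.05, smallest adjusted p = 0.422 and 0.101), and 0 with the random block or with 1 value per set. Genes called in one region and not in another, such as Dmp1 or Il33, are thus not shown to differ in effect between the jaws or between the ends. Without mutant sets 1 and 3 the difference between the jaws gave 5 calls.

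In control embryos, the comparison of mandible with maxilla asked which genes mark each jaw (n = 6 arrays each). Hand2, a transcription factor of the mandibular arch, was 20.3-fold higher in the mandible (log2 4.34 ± 0.321, adjusted p = 6.26e-07). Pax3 (2.05 ± 0.316), the matrix protease gene Mmp9 (1.86 ± 0.177), the bone sialoprotein gene Ibsp (1.82 ± 0.364), Hpse2 (2.60 ± 0.517) and Scin (1.80 ± 0.463) were also higher there. So were the cartilage genes Cnmd (2.51 ± 0.727), Acan (2.01 ± 0.607), Hapln1 (1.87 ± 0.576) and Col9a1 (1.80 ± 0.464). Higher in the maxilla were the hormone gene Crh (-3.63 ± 0.285, adjusted p = 8.41e-07), the forkhead gene Foxl2 (-2.47 ± 0.257) and its antisense partner Foxl2os (-3.23 ± 0.324), Hoxd1 (-2.52 ± 0.506) and Prph (-2.37 ± 0.384, another probe set at 0.03). The muscle genes Tnnc2 (-2.61 ± 0.356), Myh8, Tnnt2, Myl1 and Klhl41 (-2.50 to -2.38) were higher in the maxilla too.

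Skeletal muscle genes were lower in the mandible, 28 of 31 with 0 higher (28 when adjusted over the list alone; camera adjusted p = 1.1e-34, and adjusted p = 0.0572 with an estimated correlation). Tendon had 6 of 14 lower (9 lower and 1 higher when adjusted over the list alone, adjusted p = 2.17e-06), including Scx (-1.20 ± 0.148) and Kera (-1.32 ± 0.267). Neurons had 7 of 16 lower (12 when adjusted over the list alone, adjusted p = 2.99e-08), including Nefl (-1.23 ± 0.27) and Pou4f1 (-1.74 ± 0.365). Cartilage had 6 of 22 higher (13 when adjusted over the list alone, adjusted p = 7.6e-08). Bone had 7 of 16 higher (7 when adjusted over the list alone, adjusted p = 1.5e-05), including Alpl (1.03 ± 0.175), and epithelium had 11 of 24 higher (14 when adjusted over the list alone, adjusted p = 1.17e-08), including Krt14 (0.81 ± 0.113). With an estimated correlation these 5 lists gave adjusted p = 0.0572 (tendon), 0.0868 (neurons), 0.287 (cartilage), 0.067 (bone) and 0.0572 (epithelium). Maxillary identity had 5 of 18 lower, including the nuclear receptor genes Nr2f1 (-1.52 ± 0.141) and Nr2f2 (-0.77 ± 0.119). It had 8 lower and 1 higher when adjusted over the list alone (adjusted p = 9.1e-05, and adjusted p = 0.0572 with an estimated correlation). Endothelin and mandibular identity had 5 of 14 higher, including Hand2, Gsc (1.34 ± 0.258) and Dlx3 (0.82 ± 0.166), and 2 lower, among them Cited1 (-1.38 ± 0.114). There were 6 and 3 when adjusted over the list alone (adjusted p = 0.0376, and adjusted p = 0.188 with an estimated correlation). The palate list, with 4 of 25 higher and 7 lower (4 and 9 when adjusted over the list alone), held Sim2 (-2.26 ± 0.308), Meox2 (-1.82 ± 0.205) and Barx1 (-1.70 ± 0.167) but was not called (adjusted p = 0.318, median 0.02, mean -0.12). WNT signalling had 9 of 30 higher and 1 lower (11 and 2 when adjusted over the list alone, adjusted p = 0.000175, and adjusted p = 0.0572 with an estimated correlation), including the secreted inhibitor Wif1 (1.14 ± 0.149) and Sfrp2 (-0.58 ± 0.0744).

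Altogether limma called 537 genes higher in the mandible and 740 lower, and camera called 20 lists. None of the 20 held with an estimated correlation. With only the 12 arrays compared 2252 genes were called in place of 1277, and 2012 with the random block.

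The comparison of the ends of the control mandible asked which genes follow its distal to proximal axis (n = 3 arrays each). Alx1, a homeobox gene of craniofacial mesenchyme, was higher distally by log2 4.48 ± 0.566 (adjusted p = 2.39e-05) and the signalling gene Shh by 2.86 ± 0.285 (adjusted p = 4.25e-06). Also higher distally were the epithelial genes Krt6a (3.01 ± 0.39) and Dsg1a (2.60 ± 0.479), the enamel organ gene Odam (2.70 ± 0.413), Sfrp4 (2.81 ± 0.292), Them5 (3.44 ± 0.292), Klhl14 (3.30 ± 0.36), Hpse2 (2.56 ± 0.731) and Egr3 (3.09 ± 0.49, another probe set at -0.07). The largest differences towards the proximal end were the muscle genes Tnnc2 (-4.91 ± 0.504, adjusted p = 4.94e-06), Myl1, Myh3, Mylpf, Tnnt2, Mybph, Tnnc1 and Acta1 (-4.32 to -4.18), with Crh (-4.28 ± 0.402) and Tceal7 (-4.17 ± 0.466).

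Of 31 skeletal muscle genes 28 were lower distally and 0 higher (29 when adjusted over the list alone; camera adjusted p = 1.97e-35, and adjusted p = 0.0602 with an estimated correlation). Epithelium had 13 of 24 higher distally (16 higher and 1 lower when adjusted over the list alone, adjusted p = 5.52e-11), including Dsp (1.23 ± 0.122) and Cdh1 (1.14 ± 0.161). The tooth list had 9 of 21 higher and 1 lower (14 and 1 when adjusted over the list alone, adjusted p = 3.53e-05). Its Bmp4 was higher (1.36 ± 0.198) and its proximal tooth gene Barx1 lower (-3.24 ± 0.236). Both calls held with an estimated correlation (adjusted p = 0.044 each), and no other did. WNT signalling had 14 of 30 higher and 4 lower (16 and 4 when adjusted over the list alone, adjusted p = 8.49e-05), including Wnt5a (1.26 ± 0.13) and Lef1 (1.15 ± 0.156). Hedgehog signalling had 5 of 15 higher (5 when adjusted over the list alone, adjusted p = 0.000114), including Hhip (1.12 ± 0.223). Lower distally were macrophages (8 of 15, 12 when adjusted over the list alone, adjusted p = 6.69e-07), including C1qc (-0.76 ± 0.165), and TGF-beta responsive genes (8 of 27 with 1 higher, 9 and 1 when adjusted over the list alone, adjusted p = 0.00253), including Lox (-1.01 ± 0.166). So was Hox-expressing tissue (2 of 7, 6 when adjusted over the list alone, adjusted p = 0.00121), Hoxa2 (-3.27 ± 0.692) and Hoxb2 (-1.74 ± 0.422). With an estimated correlation these 5 gave adjusted p = 0.0602 (WNT), 0.0896 (hedgehog), 0.199 (macrophages), 0.0948 (TGF-beta responsive genes) and 0.268 (Hox-expressing tissue).

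In total 864 genes were higher distally and 980 lower (1844), and camera called 15 lists. With the replicate number as a block and only these 6 arrays, 2776 genes were called. The lists of cartilage (adjusted p = 0.000673) and endothelium (adjusted p = 0.0117) were gained while neural crest mesenchyme was lost (adjusted p = 0.0875, from 0.0055). With an estimated correlation and no block these 3 lists gave adjusted p = 0.874, 0.616 and 0.0714.

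In the control maxilla the distal end carried more epithelial transcripts and the proximal end more of cartilage and nerve (n = 3 arrays each). Higher distally were the keratinocyte genes Krtdap (log2 2.63 ± 0.483), Krt1 (2.45 ± 0.399), Krt5 (1.92 ± 0.195, adjusted p = 1.29e-05), Dmkn (2.43 ± 0.36), Dsg1a (2.21 ± 0.479), Pkp1 (1.83 ± 0.208) and Grhl1 (1.93 ± 0.253), with Capns2, Them5 and Pax3 (2.47, 2.00 and 1.94). Higher proximally were the cartilage genes Matn1 (-5.12 ± 1.16, adjusted p = 0.00997), Cnmd (-5.07 ± 1.03), Col9a1 (-3.82 ± 0.656), Col9a3 (-3.46 ± 0.703), Mia (-4.34 ± 0.903) and Cytl1 (-3.79 ± 0.996). The neuronal genes Prph (-4.72 ± 0.543, adjusted p = 3.39e-05, another probe set at 0.04), Stmn3 (-4.81 ± 0.74), Sncg (-4.32 ± 0.469) and the sodium channel gene Scn9a (-3.56 ± 0.593) were higher proximally too.

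Epithelium had 17 of 24 higher and 0 lower (17 when adjusted over the list alone; camera adjusted p = 1.14e-25), and the call held with an estimated correlation (adjusted p = 0.00157). Neurons had 11 of 16 lower distally (14 when adjusted over the list alone; adjusted p = 6.41e-17, and 0.0323 with an estimated correlation), and cartilage had 12 of 22 lower (18 when adjusted over the list alone; adjusted p = 7.31e-18, lost at adjusted p = 0.147 with an estimated correlation). WNT signalling had 12 of 30 higher and 2 lower (15 and 3 when adjusted over the list alone; adjusted p = 1.41e-05, and 0.0323 with an estimated correlation), including the epithelial ligands Wnt4 (1.33 ± 0.144) and Wnt6 (1.53 ± 0.211). TGF-beta responsive genes had 5 of 27 lower (9 lower and 1 higher when adjusted over the list alone; adjusted p = 2.24e-05, and 0.0323 with an estimated correlation), including Pmepa1 (-0.37 ± 0.0793) and Tnc (-0.90 ± 0.194). Endothelin and mandibular identity had 4 of 14 lower (5 when adjusted over the list alone; adjusted p = 0.000307, and 0.0436 with an estimated correlation), Dlx6 (-1.49 ± 0.228), Dlx6os1 (-1.44 ± 0.326), Foxc1 (-1.56 ± 0.405) and Dlx5 (-0.96 ± 0.185). Skeletal muscle had 0 of 31 called in either direction, with a median of -0.54 (adjusted p = 0.000307, lost at adjusted p = 0.635 with an estimated correlation).

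In total 467 genes were higher distally and 372 lower (839), and camera called 14 lists. With the replicate number as a block and only these 6 arrays 1658 genes were called and the tooth list was lost (adjusted p = 0.0906, from 0.0043, and 0.0954 with an estimated correlation and no block). Without distal array 1 or 2 549 and 444 genes were called, and without proximal array 1 or 3 485 and 447.

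**Figure D4:**
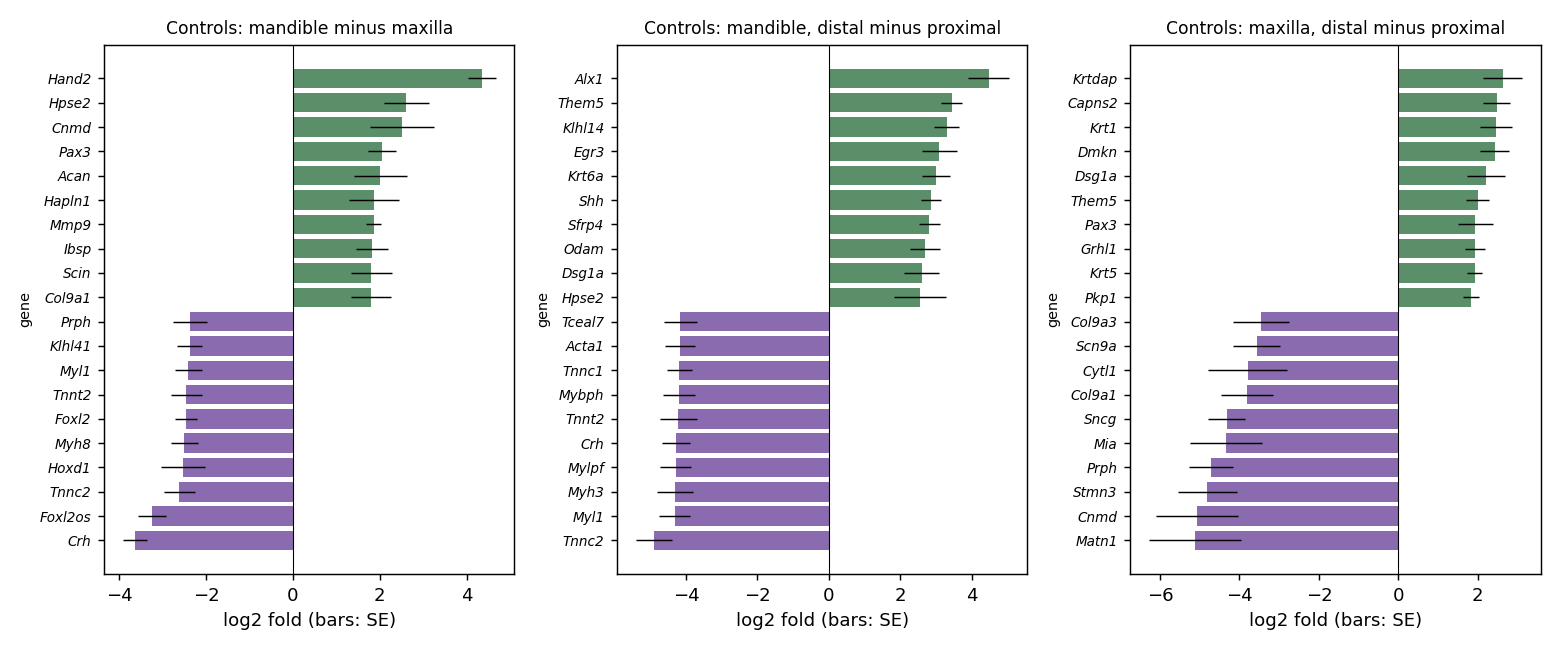
Log2 difference with SE (x axis) for the 10 genes with the largest rise and the 10 with the largest fall in each control comparison: mandible minus maxilla (n = 6 arrays each) and distal minus proximal in mandible and in maxilla (n = 3 each). Hand2 is 4.34 higher in the mandible, Tnnc2 is at -4.91 in the distal mandible, and Matn1 is at -5.12 in the distal maxilla.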

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

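Of the tests in this part, the resampled intervals and the splits of whole sets were chosen only after a result was seen, as was H2az2 as a pattern. Groups of 3 arrays are too small for a test of stray samples, but 3 arrays stood apart. The distal and proximal maxilla arrays of mutant set 1 lay at 34.6 and 34.9 on the second principal component, against 13.2 at most elsewhere, and the distal mandible array of that set had an 18S value of log2 10.90, against 13.44 to 14.60 elsewhere. Without these arrays 491, 314 and 19 genes were called in their regions, in place of 980, 789 and 124. Leaving out a control array of the same regions gave 289 to 445, 214 to 385 and 7 to 19 calls. The lower counts are thus not particular to the arrays that stood apart.

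Genes of hypoxia and glycolysis were higher in mutant arrays (18 of 24, camera adjusted p = 1.56e-07, lost at adjusted p = 0.327 with an estimated correlation). Control set 1, the control set with Y-linked transcripts, differed from control sets 2 and 3 by -0.115 of the genotype effect's median. Its 95% interval was -0.238 to 0.0236 (1000 resamples of the members). These values go against the sex of the embryos as the cause. They rest on 1 control set against 2, and the interval holds no spread between sets, so sex is not excluded. Lower RNA integrity of mutant sets 1 and 3 stays open as part of the cause: the list's median in mutant set 2, whose Gapdh probe sets read like the controls', was 0.64 of that in mutant sets 1 and 3, but with an interval of 0.0863 to 1.02. The values are consistent with a rise of hypoxia and glycolysis genes in the mutants that RNA integrity may enlarge. No test here separates an effect of the deletion from a difference in handling of the mutant embryos.

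Cell cycle genes were lower in mutant arrays (15 of 31, camera adjusted p = 1.24e-05, lost at adjusted p = 0.327 with an estimated correlation). The list also fell in mutant set 2, whose Gapdh probe sets read like the controls' (ratio to mutant sets 1 and 3 of 2.48, interval 0.994 to 15.4). This goes against lower RNA integrity as the only cause. The interval reaches below 1, so a larger fall in mutant set 2 is not shown. Control set 1 moved the opposite way (ratio -0.236, interval -0.457 to -0.0868), which goes against sex as the cause. Each ratio rests on a single set, mutant set 2 or control set 1. The intervals resample members and hold no spread between sets, so neither cause is excluded. A lower share of dividing cells in mutant jaws is a candidate explanation that was not tested.

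H2az2 changed by log2 -0.79 ± 0.0321 in mutant arrays (n = 12 arrays per genotype, adjusted p = 1.69e-11, and adjusted p = 0.00567 with 1 value per set). The 3 mutant sets stood at -0.76, -0.78 and -0.83 from the control mean. The ratio of mutant set 2 to mutant sets 1 and 3 was 0.978 (interval 0.920 to 1.05). The difference of control set 1 from the other control sets was -0.0331 of the genotype effect (interval -0.063 to 0.000616). H2az2 was picked after its values were seen, for a nearly equal fall in every region. Such a choice favours genes whose sets agree, so these ratios argue against neither RNA integrity nor sex. For this single gene the 4 regions were resampled, so the intervals hold no spread between sets. A change that comes with the mutant genotype is a candidate explanation, as a hypothesis found and tested on the same arrays. Mutants also carried the Wnt1-Cre transgene, and the Cre status of the controls is not given. For H2az2, as for any gene here, an effect of the transgene cannot be told apart from an effect of the Tgfbr2 deletion.

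The Gapdh 3' minus 5' difference averaged 0.46 in mutant set 1 and 0.54 in mutant set 3, above the highest control array (0.16), in control probe sets that enter no comparison. Among 3941 probe sets without a single gene name that passed the filter, 824 were called for the average genotype effect (481 higher and 343 lower). Apoc1, chosen after its values were seen, was lower in every mutant array of the proximal mandible than in its controls (-0.44, adjusted p = 0.0448) and higher in every mutant array of the proximal maxilla (0.55, adjusted p = 0.0166), and the difference of its effect between the jaws did not pass (-0.57, adjusted p = 0.422).

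Other splits of the same arrays were counted. For the genotype effect in a single region there are 10 splits of 6 arrays, too few for a share under 0.05; the real split called the most each time, 124 against 0 at most in the distal mandible, 742 against 5 in the proximal mandible, 980 against 13 in the distal maxilla and 789 against 11 in the proximal maxilla (1 of 10 splits as large in each). For the average genotype effect, 1 of 100 splits of single arrays called as many genes (4671 against 2792), but these splits break up the sets, whose arrays deviated together, so they do not exclude chance. The splits that keep whole sets number 10, again too few, and there the real one called 4671 and the highest other 3463. The 3 splits that put mutant sets 1 and 3 on one side and mutant set 2 on the other called 1310, 3463 and 2300 genes. This points to a structure of the samples that parts these mutant sets. The Gapdh difference parts them in the same way, but so would any other trait particular to mutant set 2. No test here tells these apart. For the differences of the genotype effect between jaws and between ends the real split called 0 genes in limma (480 and 430 at an unadjusted p under 0.05), so all 100 of 100 splits are as large by construction and the count says nothing about chance. The highest others were 3 and 720, and the 720 points to a structure of the samples. The 2 lists called for the average effect were reached by 91 of 100 splits of arrays (highest other 20) and by 7 of 10 splits of whole sets (highest other 7), so chance cannot be excluded for their number.

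In control arrays, the jaw comparison called 1277 genes against 724 at most (1 of 100 splits) and 20 lists, reached by 2 of 100 splits (highest other 20). These splits of single arrays break up the 3 control sets too, so they do not exclude chance. The splits of the distal and proximal ends number 10 in each jaw, too few for a share under 0.05. The mandible gave 1844 genes against 0 (1 of 10) and 15 lists against 13 (1 of 10), and the maxilla 839 genes against 0 (1 of 10) and 14 lists against 15 (3 of 10). Among splits that part all 3 pairs the highest others were 0 and 0 genes and 13 and 13 lists.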

How the results depend on the processing

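The alternatives chosen after seeing the data were 1 value per set, leaving out sets, the Gapdh covariate, gene-by-gene array weights, the filter on the probe set mean, the random block for lists and leaving out the genes of the X and Y chromosomes. The last gave 4511 calls for the average effect, from 4671. Counts of called genes depended on the settings given below, and the cause was not tested unless the setting itself shows it. Every alternative fixed in advance was run, but limma's array weights stopped before they converged. On arrays, signal over background limits which genes can be tested, and without the filter every count of genes stayed within 1.5 times except the 68 calls in the distal mandible (124 with the filter).

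With 1 value per set, which has fewer residual degrees of freedom and does not count the arrays of a set as separate samples, the average genotype effect gave 80 calls and 4 lists. In simulated data with arrays of a set correlated, arrays as replicates gave 556 false calls against 3 with 1 value per set. They recovered 95% of the log2 0.5 changes against 57%. Fewer false calls and lower power can thus both lower the count. The random block gave 1612 calls for the average effect (771 higher) and 68 in the distal mandible, and in control arrays 2012, 3234 and 1707 calls for the jaws and for the ends of mandible and maxilla. With only the groups of the contrast the 4 regions gave 1, 283, 0 and 5 calls (distal and proximal mandible, distal and proximal maxilla; 2059 genes at an unadjusted p under 0.05 beside the 0), the control jaws 2252 and the control maxilla 1692; for the average effect and its differences this setting holds all arrays. Array weights gave 619 and 3597 calls in distal and proximal mandible and 3146, 5046 and 3159 in the control comparisons. The gene-by-gene weights gave 3318 and 3007, 2 for the proximal minus distal difference, and 2823, 4483 and 2923.

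Control and mutant arrays of the same number and region share only a number (mean correlations 0.15, -0.02 and 0.21). The control jaws of a number correlated at 0.39, 0.09 and 0.49 and were not taken as pairs, although the sex-linked transcripts of control set 1 are alike in both jaws. The replicate block gave 310, 1120, 1488 and 1254 calls in the 4 regions. For the control jaws it was run with only the arrays compared and gave 2484, where those arrays without the block gave 2252. For the paired ends, also with only the arrays compared, it gave 2776 (mandible) and 1658 (maxilla). Those arrays without the block gave 2573 and 1692. Beyond the list calls given with those results, the block with only the arrays compared changed no other list call there.

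The mean of all probe sets gave 80, 425, 565 and 451 calls in the 4 regions and 2 for the proximal minus distal difference; with the filter on that mean, 417, 578 and 461 in the last 3 regions and 2. It turned Tgfbr2 in the proximal mandible from 0.20 to -0.058, not called before or after (with the filter on the mean, -0.058 too). The share of higher calls fell to 30.0, 41.2, 27.1 and 44.3% in the regions and 40.7% on average, from 40.3, 53.2, 42.7, 58.3 and 54.1%. Quantile normalization again kept every count within 1.5 times, but in the distal mandible 27.3% of 139 calls were higher (38 higher and 101 lower).

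Without mutant sets 1 and 3, where the lone mutant array of a group is assumed to vary like the other groups, the regions gave 794, 1330, 2423 and 2156 calls, of which 54, 416, 479 and 456 were shared, and the difference between the jaws gave 5. The average effect then gave 6597 calls (2835 shared, 40.6% higher), and 5845 with the Gapdh difference as a covariate (2705 shared, 41.5% higher). Leaving out 1 set gave 2902 (control 1), 3340, 3076 (control 3), 4353, 6971 (mutant 2) and 3876 calls. Leaving out 1 array gave 7 to 877, 139 to 556, 289 to 1692 and 214 to 773 calls in the regions, 4139 to 5264 on average, 0 to 1 and 0 to 3 for the differences between jaws and ends, 1001 to 1164 for the control jaws, and 1240 to 1511 and 444 to 726 for the ends of mandible and maxilla.

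With an estimated correlation 0, 0, 2 and 5 lists were called for the average effect, the control jaws, the mandible and the maxilla, in place of 2, 20, 15 and 14. Hypoxia and glycolysis and cell cycle were called under every other setting run with 24 arrays or without mutant sets 1 and 3; without the filter 4 lists were called, adding macrophages (adjusted p = 0.0356) and TGF-beta ligands, receptors and regulators (adjusted p = 0.0337). Leaving out 1 array gave 2 to 3, 17 to 20, 14 to 17 and 14 to 15 lists. Over all named genes and alternatives, 144 results of the average effect were no longer called. The same held for 30, 7, 30 and 24 results of the regions and 11, 5 and 15 of the control comparisons. In that order, 1286, 101, 121, 97, 108, 527, 512 and 413 kept their direction and their status. These include genes called neither before nor after. A call was gained in 3 results of the average effect, 1 of the distal mandible and 5 of the distal maxilla. Only Tgfbr2 in the proximal mandible reversed (2 alternatives).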

Other observations

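The list tests in this part, on the differences of the genotype effect, were not planned, and they were described after their results were seen. The median difference of skeletal muscle genes between mutant and control was log2 0.73 in the distal mandible and -0.74 in the distal maxilla, but -0.16 and -0.10 at the proximal ends of mandible and maxilla. No member passed in limma in any single region (3 of 31 were higher in the distal mandible when adjusted over the list alone). In control arrays most of these genes differed between the jaws and between the ends of the mandible. Whether the dissected pieces held unlike amounts of muscle in mutants and controls was not tested. The genotype effect on the list differed between the jaws by a median of 0.67 (camera adjusted p = 1.03e-16). Bone genes also differed between the jaws, by a median of 0.42 towards the mandible (adjusted p = 1.78e-07), and epithelial genes by -0.19 (adjusted p = 4.89e-05). Camera called 5 more lists for this difference (tendon, palate, macrophages, cell cycle and neural crest mesenchyme, adjusted p = 0.0016 to 0.0161), at adjusted p = 0.207 to 0.605 with an estimated correlation. With an estimated correlation skeletal muscle, bone and epithelium gave adjusted p = 0.274, 0.175 and 0.253, and 0 members of these 3 lists passed in limma for the difference (480 genes of all tested had an unadjusted p under 0.05). Between the ends the macrophage list differed by a median of 0.21, proximal minus distal (adjusted p = 2.11e-05, and adjusted p = 0.533 with an estimated correlation). Its medians were -0.33 distally and 0.17 proximally in the maxilla, but -0.20 and -0.27 in the mandible, so the 2 jaws did not go the same way. For the ends camera also called immediate early and heat shock genes, extracellular matrix, neurons, hedgehog signalling and cell cycle (adjusted p = 0.0205 to 0.0225), at adjusted p = 0.118 to 0.653 with an estimated correlation.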
